A study of Homo sapiens with 14 samples.

How the data were processed

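The series holds 14 RNA sequencing libraries of the human ovarian cancer cell lines A1847, A2780 and OVCAR5. Per the labels' protocols, cells were grown in 6-well plates and exposed to DMSO or 500 nM JQ1 for 48 h, RNA was extracted with a GeneJET kit, and libraries were made with the stranded mRNA kit of the TruSeq series. The deposited files give 1 gene table per library with FPKM, fragments scaled to transcript length and to the fragments mapped in the library, which the authors made with Cufflinks, per the submitters' processing notes. The reads were aligned with TopHat 1.0.0 to hg19, per the submitters' processing notes, and the version of Cufflinks and the gene annotation are not given in the sources used here. No scaling across libraries is recorded in the headers. FPKM are relative values, so a rise in the share of a few abundant genes lowers the others. Cufflinks divides reads among overlapping transcripts and similar copies by a model, so genes with near-identical copies or pseudogenes are uncertain.

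Each table has 25275 entries for 23609 gene symbols. Of these symbols 548 are annotated at several loci, and their values were summed, and 1751 are RNAs shorter than 200 bases, which were left out of the ranking of genes. Cufflinks marks an estimate that failed and lists it at 0, which concerned 1 to 6 entries per library. A further 274 entries in the first table carry a status of too little data and were kept. Failed values were treated as missing, and 15 genes that failed in at least 1 of the 8 libraries tested were left out. Coordinates are those of the files, in hg19, counted from 1, and give the whole locus of a gene, introns included. The reference annotation at hand is of another build and served only for transcript lengths.

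The total number of reads is not recorded in these tables. The relative depth was estimated from genes under 0.05 FPKM as the most frequent ratio to the first A1847 DMSO library, and ranged from 0.74 to 1.23. That ratio was shared by 14.9% to 22.2% of such genes, so no counts were recovered and no interval from counting error is given. Replicate libraries had a Pearson r of 0.988 to 0.99 across genes on the log2 scale, and no pair had more than 1 identical value among its expressed genes, so all were kept as separate libraries.

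Groups were taken from the titles and descriptions. In 5 libraries these disagree. An A1847 library is titled JQ1 and described as DMSO, another is titled DMSO and described as JQ1R, and the last is titled JQ1R and described as JQ1. An A2780 library is titled JQ1R and described as JQ1, and another is titled JQ1 and described as JQ1R. None of them entered a comparison of groups. A pair of the A1847 libraries entered a test of their own labels, and for A2780 only statements that hold for both exposed libraries were made.

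The planned count-based test was not used, because the files hold FPKM. The log2 of FPKM plus a pseudocount of 1 was tested with limma 3.58.1 in R 4.3.3, with an intensity trend, for 12395 genes with a mean of at least 1 FPKM over the 8 libraries. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A single fit with a mean for each of the 4 groups shared 1 estimate of the spread (4 residual degrees of freedom, 3.89 prior). It gave the JQ1 effect in A1847, in OVCAR5, their average and their difference. All tests are two-sided, p-values were adjusted by Benjamini-Hochberg, and the threshold was 0.05. The 48 gene lists, among them one of 501 protein kinases, were compared with other genes by limma's camera with a preset correlation of 0.01 where at least 5 members were tested, which left 42. Camera was also run with the correlation estimated from the data, and calls within a list were also adjusted over the list alone. With an estimated correlation camera tests on the 4 residual degrees of freedom, so few lists can pass even at a low correlation. For histone genes in A1847 the estimate was 0.004, under the preset 0.01, yet camera's adjusted p went from 1.12e-12 to 0.0527. Correlation did not undo that call, but may have undone others (0.672 for ribosomal proteins). For A2780, a ratio of at least 2-fold to the DMSO library in both exposed libraries was counted among genes with a mean of at least 1 FPKM over the 3 libraries. That count was set beside 100 simulations of noise with the shared control, drawn from the spread of the replicate libraries. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

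The fit was tested on simulated data with 200 changed genes among 12395. For A1847 it recovered 89.6%, 98.5% and 100% of those changed by a log2 of 0.5, 1 and 2, with 5.42% of its calls wrong. For OVCAR5 these were 89.6%, 95.5%, 100% and 3.55%. The real fit called far more genes, so the rates may not hold there.

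The groups, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names, for A1847 and for OVCAR5, the 8 largest rises and 8 largest falls past the threshold with both JQ1 libraries beyond both DMSO libraries, and the 6 largest of each among kinases. For the average it names the 8 largest of each past the threshold in both lines, ranked by the smaller change, and for the difference the 5 largest of each. For A2780 it names the 6 genes and 6 kinases highest and lowest by the smaller ratio, with at least 5 FPKM in at least 1 of the 3 libraries. The panel of BET inhibitor markers, BRD2 and BRD3 are named throughout, and of each list described the 4 members past the threshold with the largest change in that comparison, or all where fewer passed. A few genes that the rule takes are not reported here. Lists with members named are those that passed in A1847, OVCAR5 or the difference, the kinase lists, markers of other cell types, and a few others that were chosen after their values were seen. In A2780, where nothing is tested, list members are named only where they belong to the panel or are among those highest and lowest. Unnamed genes, short RNAs and failed genes are left out of the ranking.

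The alternatives were pseudocounts of 0.1 and 0.5 FPKM, no filter on low values, a mean of at least 5 FPKM, quantile normalization, median centring, limma without a trend, each line fitted alone, the replicate number as a block, and leaving out each of the 8 libraries in turn. Leaving out symbols with several loci and RNAs shorter than 200 bases was added after seeing the data. With a library left out, its group holds 1 library that is assumed to vary like those of the other groups.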

Results

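Messenger RNA was sequenced from 3 human ovarian cancer cell lines, A1847, A2780 and OVCAR5, in 14 libraries. The cells had received JQ1, a small molecule that displaces the BET bromodomain proteins from acetylated chromatin, or the solvent DMSO. The stated aim was to follow the RNA of protein kinases when these lines meet JQ1 briefly (500 nM for 48 h) or are kept in it chronically (JQ1R). In 4 groups the labels of every library agree and there are 2 libraries each, A1847 with DMSO, A1847 with JQ1 for 48 h, OVCAR5 with DMSO and OVCAR5 with JQ1 for 48 h, and the tests use these 8 libraries. Another A2780 library is DMSO by both its title and its description. In the other 5 libraries the title and the description name different conditions, so each is introduced below by both of its labels and afterwards named by its title, and none enters a comparison of groups.

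Expression was given as FPKM per gene. The FPKM of a library summed to between 453222 and 545450, and between 11392 and 12303 genes reached 1 FPKM. Absolute sequencing depth is unknown, and depth relative to the first A1847 DMSO library ranged from 0.74 to 1.23, as estimated from the smallest values. Replicate libraries of a group differed by a median of 0.05 to 0.12 on the log2 scale. Nothing states whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

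HEXIM1, an inhibitor of the elongation factor P-TEFb whose RNA is widely used as a marker of BET inhibitor exposure, lies at chromosome 17, 43224684 to 43229468 in hg19. It rose in A1847 from 16.1 ± 0.25 FPKM with DMSO to 57.1 ± 1.04 with JQ1 (mean ± SD, n = 2 here and below). It rose in OVCAR5 from 16.4 ± 0.15 to 55.7 ± 0.499 FPKM. The log2 changes were 1.76 ± 0.05 (± SE, adjusted p = 1.79e-07) and 1.71 ± 0.05 (adjusted p = 1.64e-07). Among the libraries with disagreeing labels, HEXIM1 stood at 41.7 FPKM in the A1847 library titled JQ1 and described as DMSO, at 41.8 in the one titled JQ1R and described as JQ1, and at 15.1 in the one titled DMSO and described as JQ1R. In A2780 it stood at 21.01 FPKM with DMSO, at 61.6 in the library titled JQ1R and described as JQ1, and at 58.6 in the library titled JQ1 and described as JQ1R.

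MYC, the proto-oncogene most often linked to BET inhibition (chromosome 8, 128748315 to 128753680), fell in OVCAR5 from 116 ± 4.5 to 69.2 ± 4.72 FPKM (log2 -0.74 ± 0.09, adjusted p = 0.000169). In A1847 it measured 62.3 ± 6.07 FPKM with DMSO and 67.6 ± 5.39 with JQ1 (log2 0.12 ± 0.09, adjusted p = 0.272), a difference that passed the threshold only when libraries were centred on their medians (log2 0.26). The 2 responses differed by 0.86 ± 0.12 (adjusted p = 0.00136). FOSL1, a subunit of the transcription factor AP-1 (chromosome 11, 65659692 to 65667997), fell in A1847 from 369 ± 5.45 to 186 ± 16.02 FPKM (adjusted p = 8.37e-06) and rose in OVCAR5 from 326 ± 4.86 to 409.8 ± 15.5 (adjusted p = 0.00326). The difference of -1.32 ± 0.10 passed the threshold (adjusted p = 4.57e-05). SERPINI1, which encodes neuroserpin (chromosome 3, 167453432 to 167543357), rose in OVCAR5 from 1.95 ± 0.0225 to 11.5 ± 0.617 FPKM (adjusted p = 1.64e-07), while no replicated A1847 library exceeded 0.0181 FPKM. In the A1847 libraries titled JQ1, JQ1R and DMSO, MYC stood at 76.6, 85.4 and 69.97 FPKM and FOSL1 at 228.3, 461.7 and 454.1. In A2780, with DMSO, in the library titled JQ1R and in the library titled JQ1, MYC stood at 112, 111 and 145 FPKM, FOSL1 at 1.07, 8.72 and 9.67, and SERPINI1 at 1.94, 9.88 and 12.1.

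**Figure D1:**
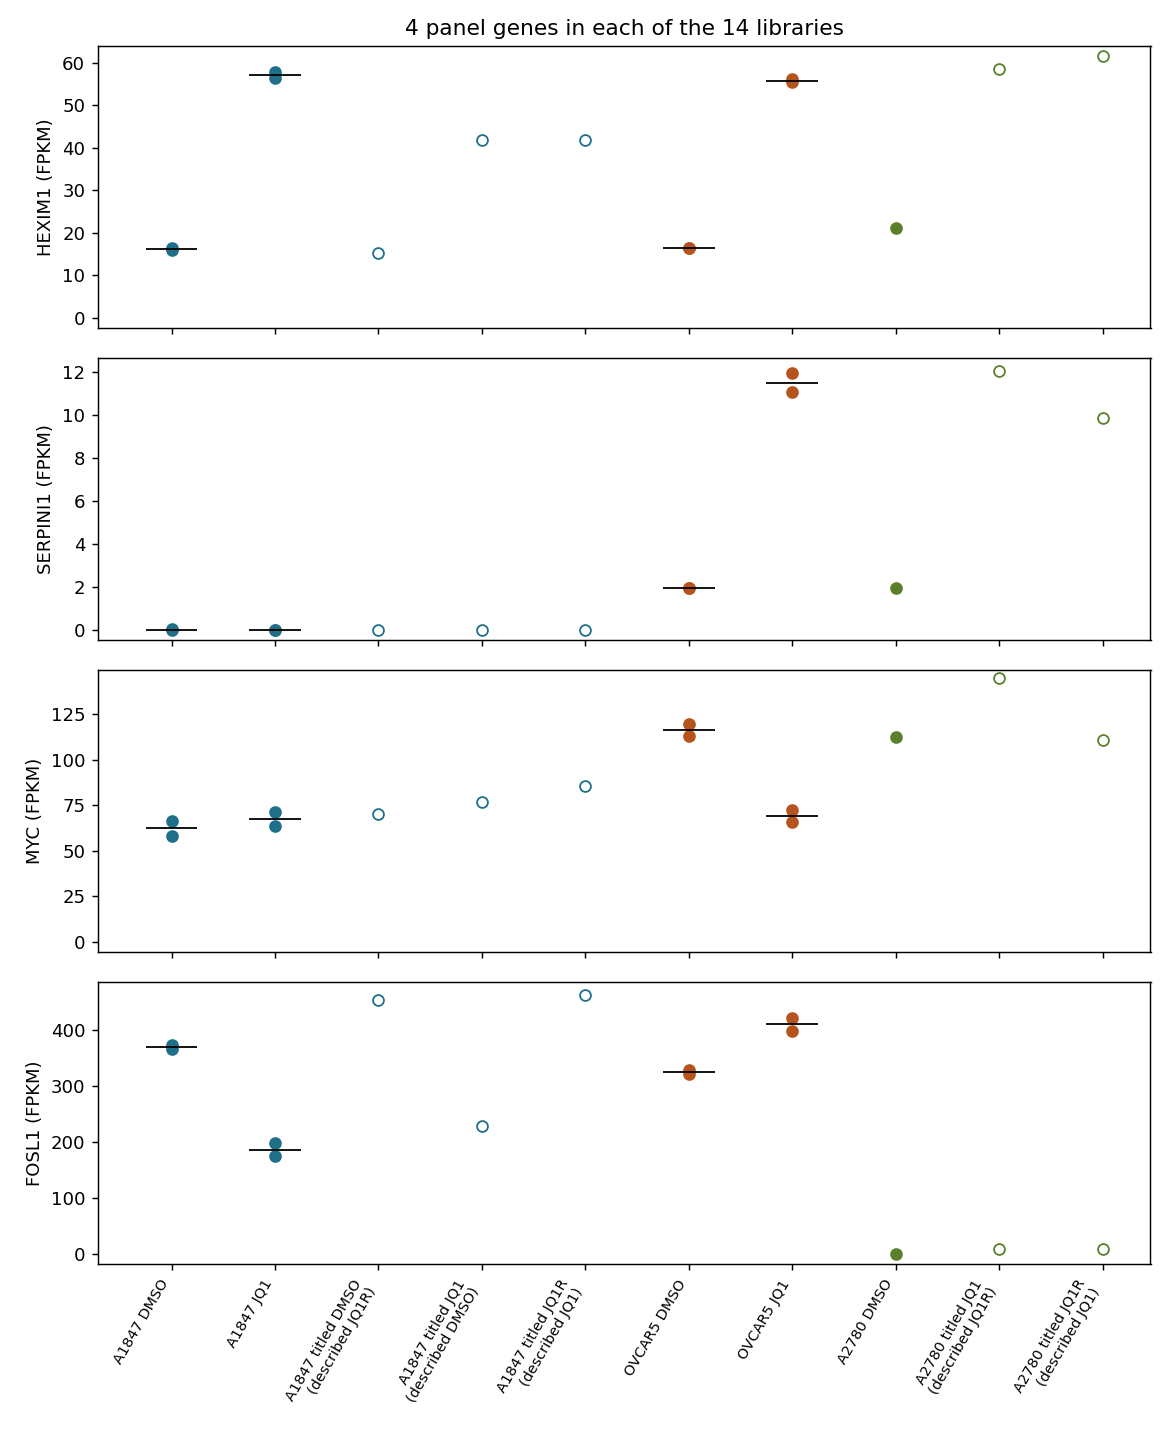
FPKM of HEXIM1, SERPINI1, MYC and FOSL1 in each of the 14 libraries, 1 panel per gene, with a black line at the mean of each pair of replicates; filled points are libraries whose labels agree and open points those whose title and description disagree. HEXIM1 lies between 55.4 and 57.9 FPKM in the 4 replicated JQ1 libraries and between 16 and 16.5 in their DMSO controls.

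Other members of the fixed panel of BET inhibitor markers moved in both lines. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 7.44 ± 0.804 to 66.2 ± 3.57 FPKM in A1847 and from 16.9 ± 0.747 to 76.6 ± 3.21 in OVCAR5. The histone genes HIST2H2BE and HIST1H2BK rose by log2 1.81 and 1.72 in A1847 and by 2.54 and 1.37 in OVCAR5, and ZCCHC24 by 1.32 and 1.53. FOXM1, a transcription factor of the G2/M programme, changed by -1.26 and -0.68, CDK6 by -1.54 and -0.58, and IL7R by -5.59 and -2.32. CCND1, which encodes cyclin D1, fell in A1847 (-0.74) and rose in OVCAR5 (0.26). E2F1 rose by 0.58 in A1847 and 0.24 in OVCAR5, where the call was lost without either DMSO library (log2 0.23 and 0.26) or either JQ1 library (0.25 and 0.23). Of the genes of BET proteins, BRD2 rose by 1.34 and 0.82 and BRD3 by 0.50 and 0.39. BRD2 is annotated at 7 loci in the files, and its values were summed over them.

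The A1847 comparison asks what 48 h of JQ1 does to gene expression in that line. Among the largest falls were those of IL7R, the interleukin 7 receptor (chromosome 5, 35856977 to 35879705), from 52.3 ± 1.54 to 0.109 ± 0.0371 FPKM, and of NNMT, nicotinamide N-methyltransferase (chromosome 11, 114166535 to 114183238), from 42.6 ± 0.855 to 0.926 ± 0.332. IGFBP3, an insulin-like growth factor binding protein, fell from 281 ± 0.255 to 12.8 ± 1.31. DHRS2, a short-chain dehydrogenase (chromosome 14, 24105573 to 24114848), rose from 3.62 ± 0.141 to 57.5 ± 5.94 FPKM, and the imprinted, retrotransposon-derived PEG10 from 76.2 ± 3.23 to 843 ± 79.5. As lists, histone genes were higher and genes of mitosis, of the extracellular matrix and of inflammatory cytokines mostly lower. With an estimated correlation these calls of limma's camera were lost (adjusted p = 0.0527, 0.205, 0.341 and 0.341). That run tests on 4 residual degrees of freedom, at estimates of 0.004, 0.063, 0.104 and 0.081 in the same order. The log2 changes were -5.59 ± 0.06 for IL7R (adjusted p = 5.2e-09), -4.51 ± 0.11 for NNMT (adjusted p = 9.22e-08), -4.36 ± 0.08 for IGFBP3, 3.66 ± 0.08 for DHRS2 (adjusted p = 5.85e-08) and 3.45 ± 0.07 for PEG10.

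Of 12395 genes tested in A1847, 3133 rose and 5062 fell with JQ1, and 366 rose and 683 fell at least 2-fold. The other largest rises were those of HIST2H4B (3.91), RRAD, a RAS-related GTPase (3.09), the linker histone gene HIST1H1C (3.07), CLU, which encodes the secreted chaperone clusterin (3.02), CDKN1A (2.99) and LOC93622 (2.98). The other largest falls were those of SFTA1P (-4.99), PLAC8 (-3.62), FAM196B (-3.55), the WNT antagonist DKK1 (-3.50) and INHBA, which encodes a subunit of activin (-3.29). HIST2H4B is annotated at 2 loci with near-identical copies, so the division of reads between them is uncertain. The median log2 change of all genes was -0.10, and it moved to 0.002 with quantile normalization and to 0.044 with median centring, so list medians are given relative to all genes. The 10 most abundant genes held 8.49% and 8.93% of the FPKM in the DMSO libraries and 11.7% and 12.1% in the JQ1 libraries. The split between directions depends on that scaling, at 4134 higher and 4062 lower with quantile normalization and 4400 and 3704 with median centring.

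Histone genes rose in A1847. Their values here and below come from an mRNA kit, and whether they stand for all histone RNA was not examined. Of 25 tested, 23 rose and 0 fell (23 and 0 adjusted over the list alone), 18 of them at least 2-fold, with a median log2 change of 1.56 relative to all genes (adjusted p = 1.12e-12, or adjusted p = 0.0527 with an estimated correlation). Within the list, which holds neither HIST2H4B nor HIST2H2AA4, the largest changes were those of HIST1H1C (3.07), HIST1H2BD (2.96), HIST2H2AA3 (2.71) and HIST3H2A (2.67). Genes of mitosis and the G2/M phase went down, 45 of 51 falling and 0 rising (0 and 46 adjusted over the list alone), with a relative median of -0.68 (adjusted p = 8.02e-09, or adjusted p = 0.205 with an estimated correlation). The largest changes were those of CCNA2 (-1.31), ESPL1 (-1.28), FOXM1 (-1.26) and PRC1 (-1.22), CCNA2 encoding cyclin A2 and ESPL1 separase. Genes of homologous recombination and the Fanconi pathway were lower, with 0 rises and 23 falls among 39 (0 and 23 adjusted over the list alone), led by FANCD2 (-1.73), RAD51AP1 (-1.09), NBN (-0.91) and FANCI (-0.83) (adjusted p = 0.0215, or adjusted p = 0.285 with an estimated correlation). That call was lost with quantile normalization (adjusted p = 0.0546).

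Genes of NF-kB and inflammatory cytokines fell in A1847, 23 of 31 going down and 4 up (4 and 23 adjusted over the list alone), with a relative median of -0.60 (adjusted p = 0.00292, or adjusted p = 0.341 with an estimated correlation). The cytokine and chemokine genes LIF (-3.11), IL6 (-2.55), CCL20 (-2.43) and IL1B (-1.72) changed most. Extracellular matrix genes and TGF-beta targets also fell (24 of 33, with 6 rising and 6 and 25 adjusted over the list alone) (adjusted p = 0.00128, or adjusted p = 0.341 with an estimated correlation). Among the members that changed most were LAMB3 (-2.86), COL1A1 (-2.40) and CTGF (2.07). LAMB3 encodes a laminin and COL1A1 a collagen, and CTGF, a matricellular growth factor, went against the list. Of 12 fibroblast markers 2 were expressed enough to be tested, COL1A1 and MFAP5 (-2.80), and both fell. Of 19 growth factor ligands, 2 rose and 15 fell (2 and 15 adjusted over the list alone), led by BDNF (-2.19), NRG1 (-1.75), FGF2 (-1.74) and PDGFC (-1.21) (adjusted p = 0.0101, or adjusted p = 0.341 with an estimated correlation). Ribosome biogenesis genes fell in 40 cases of 60 and rose in 5 (5 and 41 adjusted over the list alone), led by BRIX1 (-1.16), GAR1 (-1.0), UTP20 (-0.89) and DDX21 (-0.81) (adjusted p = 0.00693, or adjusted p = 0.285 with an estimated correlation).

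Genes of the NRF2 and oxidative stress list rose in A1847, 15 of 27 going up and 2 down (15 and 2 adjusted over the list alone), with a relative median of 0.39 (adjusted p = 0.000479, or adjusted p = 0.203 with an estimated correlation). The largest changes were those of FTL (1.86), NQO1 (1.71), TXNRD1 (1.59) and FTH1 (1.43). FTL and FTH1 encode ferritin chains and have processed pseudogenes that can share their reads. AP-1 and immediate early genes rose in 14 cases of 21 and fell in 5 (14 and 6 adjusted over the list alone), led by KLF2 (2.74), JUND (2.37), CTGF (2.07) and ATF3 (2.0), with FOSL1 among those that fell (adjusted p = 0.00226, or adjusted p = 0.454 with an estimated correlation). Cholesterol biosynthesis genes rose in 13 cases of 25 and fell in 5 (13 and 6 adjusted over the list alone), led by INSIG1 (2.12), TM7SF2 (1.5), IDI1 (1.32) and SQLE (1.12) (adjusted p = 0.0114, or adjusted p = 0.322 with an estimated correlation). Another 6 lists passed the threshold. Fatty acid synthesis genes were higher in 9 and lower in 1 of 15 cases (9 and 1 adjusted over the list alone, adjusted p = 0.0112, or adjusted p = 0.351 with an estimated correlation), led by ACSL1 (1.35), ELOVL6 (-1.01), ACSS2 (0.96) and SCD (0.82). Housekeeping genes were higher in 10 and lower in 0 of 14 (10 and 0 adjusted over the list alone, adjusted p = 0.00225, or adjusted p = 0.205 with an estimated correlation), led by GAPDH (0.98), SDHA (0.66), B2M (0.60) and TFRC (0.56). The housekeeping call was lost with quantile normalization (adjusted p = 0.0865). Targets of p53 were higher in 10 and lower in 5 of 22 (10 and 5 adjusted over the list alone, adjusted p = 0.0357, or adjusted p = 0.341 with an estimated correlation), with the largest changes in CDKN1A (2.99), TNFRSF10B (1.23), GADD45A (-1.20) and FAS (-1.15). Glycolysis genes were higher in 13 and lower in 7 of 24 (13 and 7 adjusted over the list alone, adjusted p = 0.0372, or adjusted p = 0.564 with an estimated correlation), with the largest changes in TPI1 (1.05), GAPDH (0.98), HK2 (-0.92) and PFKP (-0.74). MYC targets were lower in 37 and higher in 4 of 61 (37 and 4 adjusted over the list alone, adjusted p = 0.0238, or adjusted p = 0.593 with an estimated correlation), with the largest changes in SLC19A1 (-1.10), ODC1 (1.07), PRMT3 (-0.96) and HK2 (-0.92). Mesenchymal genes were lower in 12 and higher in 2 of 16 (12 and 2 adjusted over the list alone, adjusted p = 0.0357, or adjusted p = 0.454 with an estimated correlation), led by TGFBI (-1.70), FN1 (-1.37), NT5E (-0.98) and ZEB2 (-0.79). GAPDH lost its call in A1847 with quantile normalization (log2 0.38). The p53 call was lost without A1847 DMSO replicate 1 (adjusted p = 0.0659) or JQ1 replicate 2 (0.0552), the glycolysis call without DMSO replicate 1 (0.0693) and the MYC target call without JQ1 replicate 1 (0.0782). In genes of at least 5 FPKM the p53 and glycolysis calls were lost (0.134 and 0.147), as was p53 with median centring (0.0687) and glycolysis with quantile normalization (0.261) or A1847 fitted alone (0.0505). In all, 17 of the 42 lists tested passed, and with an estimated correlation limma's camera passed 0, with 6 at an unadjusted p under 0.05.

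Among protein kinases, the subject of the study, MKNK2, which phosphorylates the translation initiation factor eIF4E (chromosome 19, 2037470 to 2051243), rose most in A1847, from 10.6 ± 0.16 to 49.8 ± 5.03 FPKM (log2 2.13 ± 0.07, adjusted p = 2.98e-07). ULK1, which starts autophagy, rose from 3.84 ± 0.394 to 12.97 ± 1.49 FPKM. The mitotic kinase gene AURKA (chromosome 20, 54944445 to 54967351) fell from 74.02 ± 0.876 to 23.8 ± 0.312 FPKM (log2 -1.59 ± 0.05, adjusted p = 2.36e-07), and CDK6, which acts in G1, from 26.9 ± 3.19 to 8.62 ± 1.89. The other largest rises were those of TEX14 (1.61), GRK5 (1.44), ADCK5 (1.28) and MAP3K3 (1.17), and the other largest falls those of ALPK2 (-1.61), PLK2 (-1.37), PRKCH (-1.32) and HIPK3 (-1.30). Of 366 kinases tested, 88 rose and 151 fell (88 and 151 adjusted over the list alone), or 130 and 120 with quantile normalization and 133 and 115 with median centring, and 10 rose and 21 fell at least 2-fold. Mitotic and checkpoint kinases fell in 19 cases of 22, with 0 rising (0 and 19 adjusted over the list alone) (adjusted p = 0.000566, or adjusted p = 0.341 with an estimated correlation), led by AURKA (-1.59), PLK4 (-1.27), PBK (-1.25) and PLK1 (-1.08). Of 27 receptor tyrosine kinases, 6 rose and 10 fell (6 and 10 adjusted over the list alone), led by DDR1 (-1.21), FGFR3 (1.0), AXL (-0.78) and EGFR (-0.78). Non-receptor tyrosine kinases had 3 rises and 6 falls among 18 (3 and 6 adjusted over the list alone), led by ABL2 (-1.0), FYN (0.73), FER (-0.54) and CSK (-0.52). The call of FER was lost without A1847 DMSO replicate 1 (log2 -0.52). Cyclin-dependent and CDK-like kinases had 2 rises and 11 falls among 21 (2 and 11 adjusted over the list alone), led by CDK6 (-1.54), CDK18 (1.05), CDK17 (-0.51) and CDK2 (-0.46). As whole lists, kinases (adjusted p = 0.979, or adjusted p = 0.991 with an estimated correlation, with a relative median of 0.001 and a test direction of down), receptor tyrosine kinases (adjusted p = 0.916), non-receptor tyrosine kinases (0.899) and CDKs (0.748) did not pass against other genes.

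The OVCAR5 comparison asks the same of another ovarian line. CLU (chromosome 8, 27454434 to 27472328) rose from 1.47 ± 0.196 to 35.8 ± 1.62 FPKM, TM7SF2, a sterol reductase gene (chromosome 11, 64879341 to 64883707), from 4.16 ± 0.0126 to 66.1 ± 3.17, and CTGF (chromosome 6, 132269317 to 132272518) from 14.1 ± 0.132 to 196 ± 7.09. IL1B, which encodes the cytokine interleukin 1 beta (chromosome 2, 113587337 to 113594356), fell from 30.2 ± 0.569 to 0.311 ± 0.0115 FPKM, and SERPINB2, which encodes the plasminogen activator inhibitor PAI-2, from 185 ± 1.92 to 6.95 ± 0.492. As lists, histone genes were higher here too, and genes of ribosome biogenesis, MYC targets and cytosolic ribosomal proteins mostly lower. With an estimated correlation these calls were lost (adjusted p = 0.0995, 0.0995, 0.386 and 0.632). The estimates were 0.004, 0.013, 0.154 and 0.672 in the same order. The log2 changes were 3.90 ± 0.09 for CLU (adjusted p = 5.22e-08), 3.70 ± 0.10 for TM7SF2, 3.70 ± 0.07 for CTGF, -4.57 ± 0.07 for IL1B (adjusted p = 2.4e-08) and -4.55 ± 0.10 for SERPINB2.

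In OVCAR5, 3543 of the 12395 genes rose and 4210 fell, 360 and 555 of them at least 2-fold, around a median of -0.02. The split was 3891 higher and 3686 lower with quantile normalization and 3693 and 4016 with median centring. The 10 most abundant genes held 6.14% and 6.26% of the FPKM with DMSO and 8.01% and 8.31% with JQ1. Other leading rises were those of DHRS2 (3.30), HIST2H4B (3.01), the transcriptional repressor HES6 (2.96), EFR3B (2.84) and HIST1H2BD (2.78). Other leading falls were those of the activin-binding FST (-4.53), the keratin gene KRT23 (-4.38), INHBA (-4.24), the interleukin 1 alpha gene IL1A (-4.08), TM4SF18 (-3.88) and S100A2 (-3.81).

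Of 25 histone genes, 21 rose and 0 fell in OVCAR5 (21 and 0 adjusted over the list alone), with a relative median of 1.01 (adjusted p = 4.15e-08, or adjusted p = 0.0995 with an estimated correlation), led within that list by HIST1H2BD (2.78), HIST2H2AA3 (2.73), HIST1H2AC (2.63) and HIST1H2BC (2.60). Ribosome biogenesis genes fell in 51 cases of 60 and rose in 0 (0 and 52 adjusted over the list alone), with a relative median of -0.38 (adjusted p = 4.15e-08, or adjusted p = 0.0995 with an estimated correlation), led by GAR1 (-1.40), BRIX1 (-1.08), NIP7 (-0.91) and NAT10 (-0.81). MYC targets fell in 49 cases of 61 and rose in 3 (3 and 50 adjusted over the list alone), led by SORD (-1.60), SLC19A1 (-1.51), MCM5 (-1.43) and TMEM97 (-1.05) (adjusted p = 8.64e-08, or adjusted p = 0.386 with an estimated correlation). Cytosolic ribosomal protein genes fell in 40 cases of 56 with 0 rising (0 and 41 adjusted over the list alone), led by RPL29 (-0.75), RPL34 (-0.67), RPL30 (-0.59) and RPS23 (-0.58) (adjusted p = 4.9e-05, or adjusted p = 0.632 with an estimated correlation). E2F targets and DNA replication genes fell in 29 cases of 51 and rose in 8 (8 and 30 adjusted over the list alone), led by MCM5 (-1.43), E2F2 (-1.20), E2F8 (-0.93) and POLE2 (-0.88) (adjusted p = 0.00936, or adjusted p = 0.386 with an estimated correlation). Genes of mitosis and the G2/M phase fell in 30 cases of 51 and rose in 4 (4 and 32 adjusted over the list alone), led by UBE2C (-1.04), CDC25A (-0.80), PRC1 (-0.79) and CCNA2 (-0.76) (adjusted p = 0.00266, or adjusted p = 0.386 with an estimated correlation).

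NF-kB and inflammatory cytokine genes fell in OVCAR5, 21 of 31 going down and 5 up (5 and 21 adjusted over the list alone), led by IL1B (-4.57), IL1A (-4.08), IL6 (-3.33) and CSF2 (-2.65) (adjusted p = 0.000964, or adjusted p = 0.386 with an estimated correlation). Extracellular matrix genes and TGF-beta targets fell in 19 cases of 33 and rose in 4 (4 and 19 adjusted over the list alone) (adjusted p = 0.0133, or adjusted p = 0.432 with an estimated correlation), with the largest changes in CTGF (3.70), PMEPA1 (-2.69), TGFB2 (-2.41) and TNC (-1.78). AP-1 and immediate early genes rose in 11 cases of 21 and fell in 5 (11 and 5 adjusted over the list alone), led by CTGF (3.70), JUND (1.95), ZFP36 (1.43) and EGR1 (1.39) (adjusted p = 0.0232, or adjusted p = 0.485 with an estimated correlation). That call was lost in the genes of at least 5 FPKM (0.077). In the NRF2 and oxidative stress list 16 of 27 rose and 6 fell (16 and 8 adjusted over the list alone) (adjusted p = 0.0232, or adjusted p = 0.386 with an estimated correlation), a call lost without a filter on low values (0.0637) or with OVCAR5 fitted alone (0.0553). Its members with the largest changes, AKR1B10 (-2.79), SLC7A11 (-1.82), FTL (1.72) and OSGIN1 (1.65), went opposite ways. The BET inhibitor marker panel also passed (adjusted p = 0.0303, or 0.403 with an estimated correlation). It had 10 rises and 4 falls among 15 (10 and 4 over the list alone). HIST2H2BE (2.54), IL7R (-2.32), CDKN1A (2.11) and SERPINI1 (2.09) led. The call was lost under 4 other settings (0.0514 to 0.149), with none in A1847 (0.1685) or on average (0.1279). In all, 12 of 42 lists passed, mitotic and checkpoint kinases among them, and with an estimated correlation limma's camera passed 0, with 3 at an unadjusted p under 0.05.

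**Figure D2:**
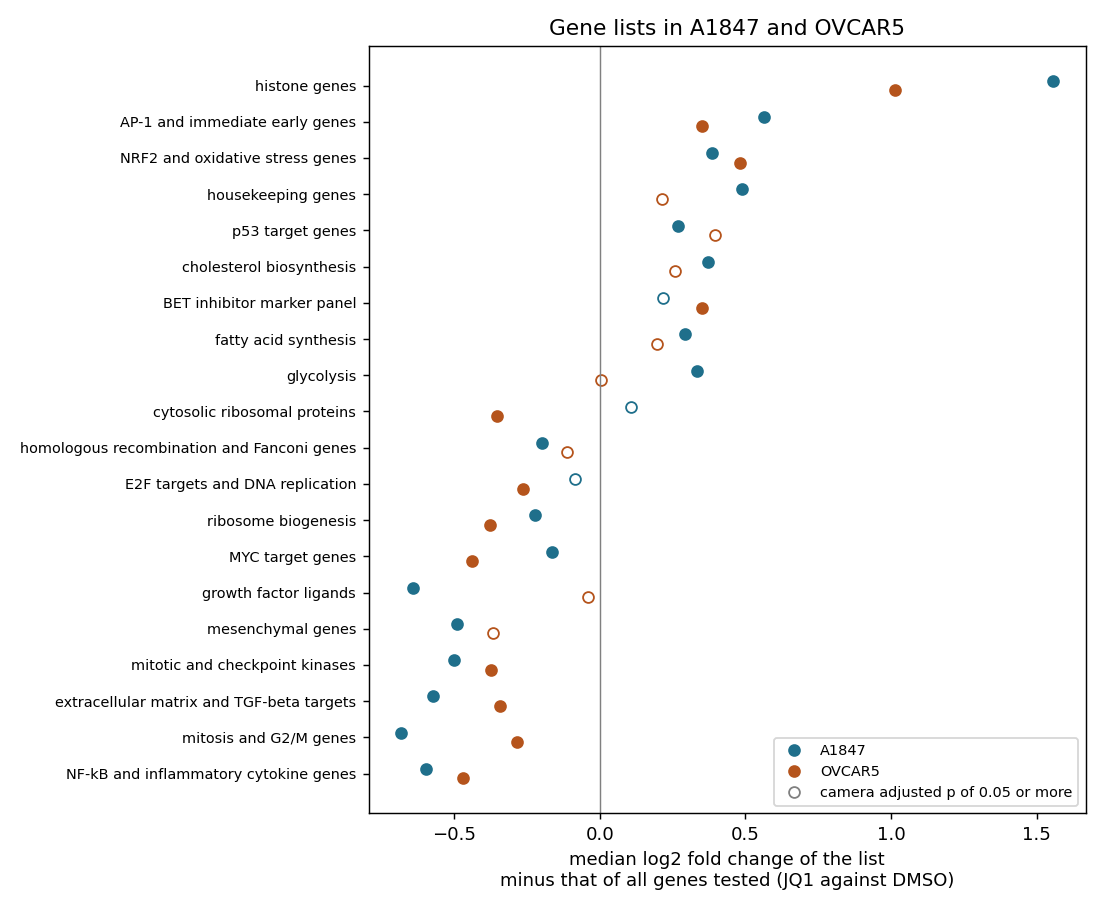
Median log2 fold change with JQ1, relative to the median of all genes, for 20 gene lists in A1847 and OVCAR5; filled points passed limma's camera at the preset correlation and open points did not. Histone genes lie highest in both lines, at 1.56 in A1847 and 1.01 in OVCAR5.

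Kinase genes in OVCAR5 included rises of fibroblast growth factor receptors and falls of MLKL, the pseudokinase that executes necroptosis (chromosome 16, 74705753 to 74734789). FGFR3 (chromosome 4, 1795039 to 1810599) rose from 2.5 ± 0.171 to 9.85 ± 0.324 FPKM (log2 1.63 ± 0.07, adjusted p = 8.47e-07) and FGFR1 (chromosome 8, 38268656 to 38326352) from 29.2 ± 0.205 to 79.7 ± 3.66. MLKL fell from 6.75 ± 0.226 to 0.692 ± 0.0108 FPKM (log2 -2.20 ± 0.06, adjusted p = 1.52e-07). ULK1 had the largest rise (1.65), and GRK5 (1.39), STRADA (1.33) and PIM2 (1.29) followed. TRIB3, a pseudokinase gene of the ATF4 response (-1.71), the receptor tyrosine kinase TYRO3 (-1.55), PTK6 (-1.51), MOK (-1.40) and MAPK3, which encodes ERK1 (-1.37), fell. Of 366 kinases, 118 rose and 98 fell (117 and 97 adjusted over the list alone), 12 and 14 of them at least 2-fold. The kinases that rose and fell numbered 134 and 85 with quantile normalization and 125 and 95 with median centring. Mitotic and checkpoint kinases fell in 14 cases of 22 with 0 rising (0 and 14 adjusted over the list alone), led by AURKA (-1.0), PLK1 (-0.81), TLK1 (-0.76) and PKMYT1 (-0.75) (adjusted p = 0.00895, or adjusted p = 0.403 with an estimated correlation). Receptor tyrosine kinases had 12 rises and 6 falls among 27 (12 and 6 adjusted over the list alone), led by FGFR3 (1.63), TYRO3 (-1.55), FGFR1 (1.42) and EPHB4 (-1.10). Non-receptor tyrosine kinases had 6 and 5 among 18 (6 and 5 adjusted over the list alone), led by PTK6 (-1.51), SRC (-1.31), SYK (-1.23) and FYN (1.15). CDKs had 5 and 4 among 21 (5 and 4 adjusted over the list alone), led by CDK4 (-0.86), CDKL1 (-0.64), CDK6 (-0.58) and CDK5 (-0.54). As whole lists, kinases (adjusted p = 0.234, or adjusted p = 0.714 with an estimated correlation), receptor tyrosine kinases (adjusted p = 0.234), non-receptor tyrosine kinases (0.688) and CDKs (0.953) did not pass.

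**Figure D3:**
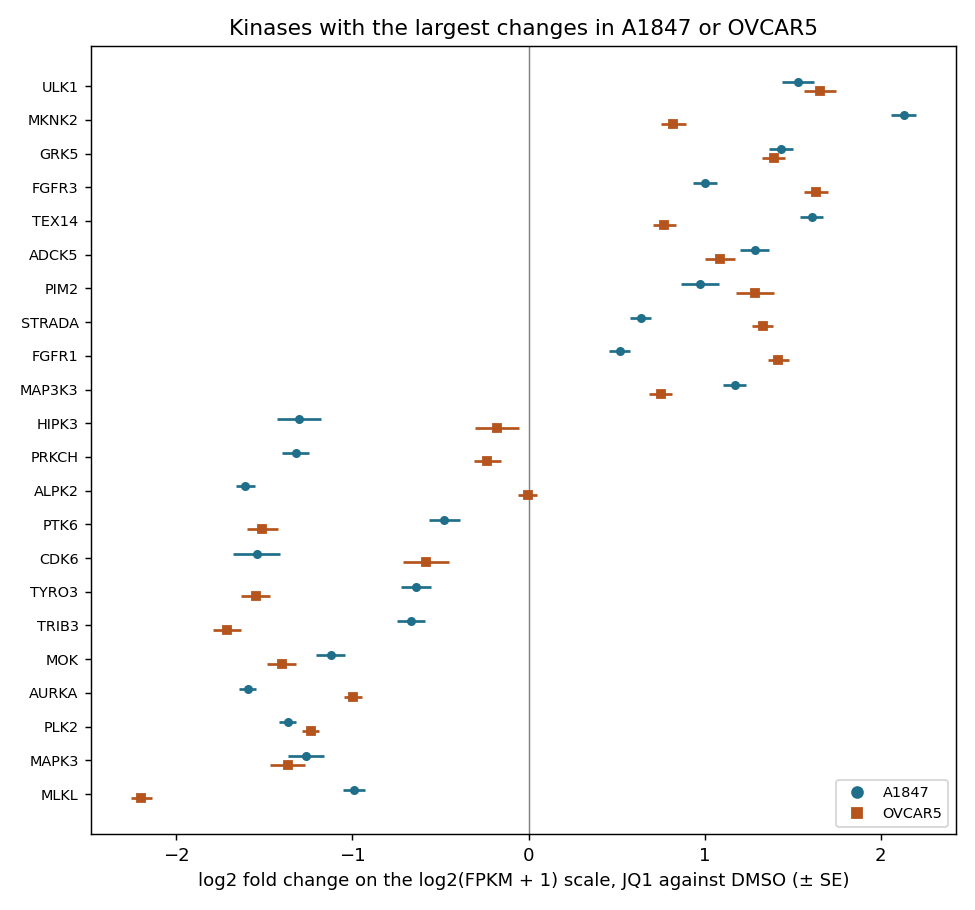
Log2 fold change with JQ1 of 22 protein kinase genes in A1847 and OVCAR5, with bars for ± 1 SE. MKNK2 lies highest in A1847 at 2.13 and MLKL lowest in OVCAR5 at -2.20.

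Many genes moved the same way in both lines. DHRS2, CLU, HIST2H4B, HIST1H2BD, the histone gene copies HIST2H2AA3 and HIST2H2AA4, PEG10 (2.45 in OVCAR5) and RRAD (2.42) had the largest shared rises. INHBA, PLAC8 (-3.19), ANXA8 and ANXA8L2, SERPINB2 (-2.94 in A1847), S100A2 (-2.72), GTF3C6, which encodes a subunit of the RNA polymerase III factor TFIIIC, and IL6 had the largest shared falls. HIST2H2AA3 and HIST2H2AA4 each rose by log2 2.71 in A1847 and 2.73 in OVCAR5. ANXA8 and ANXA8L2 measured -3.22 and -3.0 in A1847 and -3.18 and -3.75 in OVCAR5, and reads cannot be assigned with confidence between the near-identical copies of either pair. GTF3C6 (chromosome 6, 111279763 to 111289091) changed by log2 -2.69 ± 0.07 in A1847 and -2.67 ± 0.07 in OVCAR5. Genes that rose in both lines numbered 2156, against 895.5 from independent lists, and those that fell in both 3078, against 1719.3. At 2-fold the shared rises were 155 (10.6 from independent lists) and the shared falls 204 (30.6), and of 5738 genes past the threshold in both lines 504 moved in opposite directions. Across genes, which are not independent replicates, the fold changes of the lines had a Pearson r of 0.598 and a Spearman rho of 0.664. On average over the lines 3803 genes rose and 5445 fell, or 4569 and 4566 with quantile normalization and 4565 and 4517 with median centring. Of the lists 16 of 42 passed (with an estimated correlation 0, and 5 at an unadjusted p under 0.05). Histone genes led these (25 of 25 higher, 25 adjusted over the list alone, adjusted p = 3.35e-11, or adjusted p = 0.0665 with an estimated correlation), and HIST1H2BD (2.87), HIST2H2AA3 (2.72), HIST1H1C (2.50) and HIST1H2AC (2.29) changed most within that list.

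The test of the difference compares the change of a gene in A1847 with that in OVCAR5 on the log2(FPKM + 1) scale, on which a gene near 0 FPKM in a line can hardly change there. KRT23 (chromosome 17, 39078952 to 39093836) went from 0 ± 0 to 0.00685 ± 0.00969 FPKM in A1847 and from 47.7 ± 1.62 to 1.34 ± 0.12 in OVCAR5, and FST from 0.358 ± 0.151 to 0.15 ± 0.0516 and from 33.3 ± 0.706 to 0.486 ± 0.0408. FST also fell in A1847 (-0.24, adjusted p = 0.0369), a call lost under 4 other settings (log2 -0.24 to -0.09). It was also lost without A1847 DMSO replicate 1 (-0.12), A1847 JQ1 replicate 1 (-0.19) or any OVCAR5 library (-0.24). NNMT fell in A1847 as given and stayed under 1 FPKM in OVCAR5 (0.103 ± 0.0345 and 0.00842 ± 0.0119), where it passed as a fall with a pseudocount of 0.1 FPKM (log2 -0.90, adjusted p = 0.00835). IL7R fell in both lines, from 4.44 ± 0.114 to 0.0868 ± 0.0377 FPKM in OVCAR5, and IGFBP3 measured 0.0665 ± 0.0345 and 0.0646 ± 0.0605 FPKM there. The differences in log2 change, A1847 minus OVCAR5, were 4.39 ± 0.09 for KRT23 (adjusted p = 2.7e-07), 4.29 ± 0.12 for FST, 3.87 for TM4SF18, 3.76 for DHRS9, a retinol dehydrogenase gene, and 3.65 for IL1A. In the other direction they were -4.38 ± 0.15 for NNMT (adjusted p = 1.28e-06), -4.35 ± 0.11 for IGFBP3, -3.26 for IL7R, -3.15 for GREM1, a BMP antagonist, and -2.99 for LAMB3. The response differed in 4726 genes, 1807 with the higher value in A1847 and 2919 with the lower, or 2240 and 2291 with quantile normalization and 2763 and 1879 with median centring. Of the 4726, 801 had means under 1 FPKM in both groups of a line, as had 250 of the 604 that differed by at least 2-fold, and their values rest largely on the other line. Without OVCAR5 DMSO replicate 2 the count was 3135.

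Among kinases the response differed in 154 of 366, with 39 higher and 115 lower in A1847 (41 and 118 adjusted over the list alone), or 53 and 87 with quantile normalization and 68 and 72 with median centring. Without OVCAR5 DMSO replicate 1 or 2 or JQ1 replicate 2 these were 99, 92 and 97. The largest differences were those of ALPK2 (-1.60), SGK223 (-1.37), MKNK2 (1.31) and CAMK2D (-1.28). MLKL differed by 1.21 ± 0.09 (adjusted p = 4.44e-05), MKNK2 by 1.31 ± 0.10 (adjusted p = 6.14e-05), AURKA by -0.60 ± 0.07 (adjusted p = 0.00049), FGFR1 by -0.90 ± 0.09 (adjusted p = 0.000162) and FGFR3 by -0.63 ± 0.10 (adjusted p = 0.00182). ULK1 measured -0.13 ± 0.13 (adjusted p = 0.469) and GRK5 0.04 ± 0.10 (adjusted p = 0.743). Of the gene lists 12 of 42 passed, and with an estimated correlation limma's camera passed 0, with 6 at an unadjusted p under 0.05. Cytosolic ribosomal proteins were higher in A1847 relative to OVCAR5 in 31 cases of 56 and lower in 0 (40 and 0 adjusted over the list alone), among them RPL3 (0.77), RPL13 (0.58) and RPL34 (0.53) (adjusted p = 1.26e-10, or adjusted p = 0.709 with an estimated correlation). Their relative median of 0.41 became 0.04 with quantile normalization, where the call was lost (adjusted p = 0.319). In A1847 alone these genes split into 15 rises and 10 falls (14 and 9 adjusted over the list alone, adjusted p = 0.253), led by RPL28 (0.64), RPL13 (0.59), RPS2 (0.58) and RPL30 (-0.54). Their relative median there turned from 0.11 to -0.17 with quantile normalization, where the call of RPS2 was lost (log2 0.14). MYC targets were higher in 21 cases of 61 and lower in 1 (21 and 1 adjusted over the list alone), led by SORD (1.24), DCTPP1 (0.83), SLC29A2 (-0.80) and RRP9 (0.63) (adjusted p = 1.07e-05, or adjusted p = 0.512 with an estimated correlation). Mitosis genes were higher in 1 and lower in 34 of 51 (2 and 36 adjusted over the list alone), led by ANLN (-1.08), ASPM (-1.0), KIF18A (-0.90) and KIF23 (-0.82) (adjusted p = 7.14e-06, or adjusted p = 0.326 with an estimated correlation).

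For A2780 there is 1 DMSO library, so differences have no replicate check and no p-value is given. Both exposed libraries carry JQ1 labels of some kind, but their titles and descriptions disagree on which had JQ1 for 48 h and which was JQ1R, and only statements that hold for both are made. SAT1, the enzyme that acetylates spermidine (chromosome X, 23801275 to 23804327), stood at 3.6 FPKM with DMSO, 90.6 in the library titled JQ1R and 102 in the library titled JQ1. In the same order CTGF stood at 2.16, 131 and 37.1, the nuclear RNA NEAT1 at 79.4, 1171 and 863, and HIST2H4B at 0.641, 29.4 and 21.8, with the copies HIST2H2AA3 and HIST2H2AA4 also among the 6 highest. The lowest were the kinase gene MATK (chromosome 19, 3777967 to 3801810) at 22.2, 0.427 and 0.426, MMRN1 at 40.8, 0.176 and 2.12, TYRP1 at 58.3, 2.36 and 4.73, the decorin gene DCN at 110.0, 10.6 and 5.54, and MUC15 and VMO1. Of 11671 genes, 316 were at least 2-fold higher in both libraries and 578 at least 2-fold lower, or 387 and 442 with quantile normalization and 361 and 498 with median centring. The median log2 ratio of all genes was -0.125 in the library titled JQ1R and -0.051 in the library titled JQ1. Independent lists would share 31.6 and 85.9, and noise against the shared control gave a mean of 10.04 and 10.06 in 100 simulations, with at most 18 and 20. Part of the excess may come from the shared control, which a single library does not allow to be split.

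Kinases in A2780 that were higher in both libraries were led by MAP3K14, the NF-kB-inducing kinase, at 9.34 FPKM with DMSO and 48.4 and 43.8 in the libraries titled JQ1R and JQ1. TRIB1, MAP2K3, MKNK2 (29.8, 88.8 and 76.9), TNK2 and JAK1 (8.89, 22.9 and 23.99) followed. After MATK, the lowest were TYRO3 at 7.29, 0.889 and 0.74, IKBKE, PBK, MAPKAPK3 and AURKA at 28.4, 9.76 and 9.85. Of 350 kinases, 17 were at least 2-fold higher and 21 at least 2-fold lower in both, or 17 and 16 with quantile normalization and 17 and 18 with median centring. Among the panel, CDKN1A stood at 8.56, 82.1 and 41.8 FPKM, and the cyclin D2 gene CCND2 at 200.2, 11.2 and 134.

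Gene lists in A2780 are placed by the percentile of their median among 10000 random lists matched on expression, as a description of these libraries. Of 33 histone genes 33 were higher in both libraries, with median log2 ratios of 1.70 in the library titled JQ1R and 1.92 in the library titled JQ1 (percentiles 100 and 100). Of 51 mitosis and G2/M genes 49 were lower in both (-1.20 and -0.81, percentiles 0 and 0), as were 21 of 22 mitotic and checkpoint kinases (-1.11 and -0.78, percentiles 0 and 0). MYC targets were lower in 50 cases of 60 (-0.50 and -0.63, percentiles 0 and 0). All protein kinases had medians of -0.06 and 0.01 (percentiles 92.5 and 87.1). Of the 137 genes with a value among those that rose at least 2-fold in both other lines, 117 (85.4%) were higher in both A2780 libraries, and of the 126 that fell there 107 (84.9%) were lower. Over all genes compared these shares were 33.8% and 46.2%.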

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

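The label tests were fixed before their result was seen, whereas the tests of abundant genes, of ribosomal proteins and of other splits of the libraries were chosen only after the result was seen.

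HEXIM1 stood above both A1847 DMSO libraries in 2 libraries that no comparison uses, at 41.71 FPKM in the one titled JQ1 and described as DMSO and at 41.77 in the one titled JQ1R and described as JQ1. A misplaced label is a candidate explanation, and 2 forms of it were tested with the 2150 genes that rose and 3076 that fell in both lines and have a value in every library, as the mean log2 value of the former minus that of the latter. The library described as DMSO lay 1.181 above the library titled DMSO on this measure, where replicates differ by at most 0.026, which argues against the descriptions as they stand. The reverse difference of -1.181 is what correct titles predict for this pair of libraries, but the values cannot show which of the JQ1 and JQ1R labels is right. A biological explanation, such as a control that responded like treated cells, was not tested, and the libraries stay out of the comparisons.

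In A1847 more genes fell than rose, 5062 against 3133. The estimated share of fragments held by the 100 most abundant genes went from 25.3% to 31.27% with JQ1. This would shift others by a log2 of -0.12 (from -0.149 to -0.092 over 4 pairs of libraries). The observed median shift was -0.10 (from -0.117 to -0.085). Both shifts describe the same other genes in the same libraries, and would be alike whether those genes fell or were only rescaled. The excess of falls may come from the FPKM scale, but this comparison cannot decide it. In OVCAR5, where the share went from 24.53% to 25.16%, the predicted shift was -0.012 and the observed one -0.02. A global loss of RNA per cell would not be visible in FPKM and was not tested.

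Cytosolic ribosomal protein genes responded differently in the lines (adjusted p = 1.264e-10, or adjusted p = 0.709 with an estimated correlation), with a median difference in log2 change of 0.34. Lists of other genes matched on abundance had a median of 0.192, with a central 95% of 0.127 to 0.279, so a shift shared by abundant genes could account for part of the value. Quantile normalization, which removes such a shift, ended the call (adjusted p = 0.319). A difference in the response of these genes and a difference in scale cannot be told apart here, since the test that removes one may also remove the other. No biological explanation was tested.

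The response to JQ1 differed between the lines in 4726 genes, 154 of them protein kinases, by the test of the difference itself. The splits of the libraries bear on the change with JQ1 on average over the lines, not on this difference. With the cell line as a term, 34 splits of the 8 libraries into 4 against 4 could be fitted, the split by cell line itself being left out. That fit has no term for a response that differs between the lines, and in it the real split called 7272 genes, against 9248 in the fit with a mean for each group. The highest of the others called 21. The real split was the 1 of the 34 that reached its own count, so chance can be excluded for the average only if libraries are exchangeable across the lines. The splits with 2 against 2 libraries in each line number 18, of which 1, the real one, reached 7272 and the highest other called 21. These are too few for a share under 0.05. The gene count of the difference fell to 3135 without OVCAR5 DMSO replicate 2, and that of kinases to 99 and 92 without OVCAR5 DMSO replicates 1 and 2 and to 97 without OVCAR5 JQ1 replicate 2.

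Of the 225 genes named here and tested, 178 passed the test of the difference, which is what brings them here. The values are the log2 change in A1847 minus that in OVCAR5. Higher in A1847 were 93 genes. KRT23 had 4.39, FST 4.29, TM4SF18 3.87, DHRS9 3.76, IL1A 3.65, IL1B 2.85, LOC93622 2.83, DDIT4 2.83 and AKR1B10 2.75. SEMA3A had 2.49, CSF2 2.26, IFITM2 2.15, CEACAM6 2.11, HIST3H2A 1.98, HIST1H2AE 1.96, IFITM1 1.91, KRT20 1.89 and PMEPA1 1.77. KLF2 had 1.71, OASL 1.69, SDF2L1 1.62, SERPINB2 1.61, HIST1H2BF 1.42, ATF3 1.34, MKNK2 1.31, SEMA4A 1.30 and EFNB2 1.28. SORD had 1.24, SYK 1.21, MLKL 1.21, TGFB2 1.20, CDK18 1.19, EPHB4 1.19, HIST1H1C 1.14, SCD 1.12 and S100A2 1.09. PROM2 had 1.05, TRIB3 1.04, PTK6 1.03, PEG10 1.0, TNFRSF10B 0.96, INHBA 0.95, BCL2L11 0.92, TYRO3 0.91 and HIST2H4B 0.91. CDKN1A had 0.88, CDX2 0.86, MYC 0.86, SRC 0.86, TEX14 0.84, DCTPP1 0.83, IL6 0.78, RPL3 0.77 and ANXA8L2 0.75. SQLE had 0.74, NQO1 0.71, INSIG1 0.67, RRAD 0.67, TPI1 0.64, WFDC2 0.63, RRP9 0.63, IFIT3 0.62 and TMEM97 0.62. IMP3 had 0.60, PES1 0.59, RPL13 0.58, CDK4 0.57, E2F2 0.57, MCM5 0.54, BOP1 0.54, NOLC1 0.54 and RPL34 0.53. RPS2 had 0.53, ACSS2 0.53, BRD2 0.52, FTH1 0.52, GAPDH 0.51, TXNRD1 0.48, ODC1 0.47, MAP3K3 0.42 and SLC19A1 0.41. JUND had 0.41, CD68 0.40, GAR1 0.39, PAX8 0.39, ACTB 0.38, NAT10 0.38, DHRS2 0.36, HIST1H2BK 0.35 and E2F1 0.34. PPIA had 0.32, PGK1 0.26 and B2M 0.26.

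Lower in A1847 were 85 genes, again by the log2 change in A1847 minus that in OVCAR5. NNMT had -4.38, IGFBP3 -4.35, IL7R -3.26, GREM1 -3.15, LAMB3 -2.99, MFAP5 -2.78, COL1A1 -2.77, FAM196B -2.57 and SFTA1P -2.52. EGR1 had -2.36, TM7SF2 -2.20, KRT7 -2.19, SERPINI1 -2.10, NRG1 -1.76, FGF2 -1.72, CTGF -1.63, ALPK2 -1.60 and BIRC3 -1.53. DKK1 had -1.5, GADD45A -1.43, SGK223 -1.37, OSGIN1 -1.32, ETV5 -1.32, SRXN1 -1.32, FOSL1 -1.32, CAMK2D -1.28 and BDNF -1.27. SEMA7A had -1.22, LIF -1.16, PDGFC -1.16, HIPK3 -1.12, PRKCH -1.09, ANLN -1.08, EFR3B -1.04, ETV4 -1.02 and AXL -1.02. ASPM had -1.0, CCND1 -1.0, ELOVL6 -1.0, KRT19 -0.97, GCLM -0.97, CDK6 -0.96, FGFR1 -0.90, KIF18A -0.90 and CLU -0.88. TGFBI had -0.88, FER -0.85, FANCD2 -0.85, KIF23 -0.82, ZEB2 -0.81, SLC29A2 -0.80, IRF7 -0.79, EGFR -0.75 and FN1 -0.75. HIST1H2BC had -0.74, NBN -0.74, PBK -0.74, HIST2H2BE -0.73, MELK -0.72, PLK4 -0.71, STRADA -0.69, FANCI -0.69 and ABL2 -0.67. HIST1H2AC had -0.67, HES6 -0.67, CFLAR -0.64, FGFR3 -0.63, HMGA2 -0.61, FAS -0.61, AURKA -0.60, ESPL1 -0.59 and E2F8 -0.59. FOXM1 had -0.57, CCNA2 -0.55, NEU1 -0.54, CDK17 -0.51, MAP1LC3B -0.50, DDR1 -0.48, CASP9 -0.48, CDK2 -0.47 and PLAC8 -0.43. PRC1 had -0.43, FYN -0.42, PFKP -0.35 and PLK1 -0.27.

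Some of these calls were lost when 1 library was left out, and the log2 difference without it is given here. Leaving out a library also leaves less data for the spread, so a lost call need not mean that the difference rests on that library. EGFR, for example, went from -0.75 to -0.81 without A1847 DMSO replicate 1. DHRS2, E2F1 and SLC19A1 lost the call under 6 of these removals and B2M under 7. Without A1847 DMSO replicate 1 the call was lost for ACTB (0.34), B2M (0.30), BOP1 (0.43), CD68 (0.32), CDK17 (-0.39), DHRS2 (0.33), E2F1 (0.26), EGFR (-0.81), FER (-0.83), JUND (0.37), PAX8 (0.35), PGK1 (0.25), PPIA (0.28), RPS2 (0.44) and SLC19A1 (0.28). Without A1847 DMSO replicate 2 the call was lost for B2M (0.22), DHRS2 (0.39), EGFR (-0.69), PFKP (-0.27), PLK1 (-0.21) and TXNRD1 (0.45). Without A1847 JQ1 replicate 1 the call was lost for B2M (0.19) and PLK1 (-0.28). Without A1847 JQ1 replicate 2 the call was lost for CD68 (0.33), CDK17 (-0.35), E2F1 (0.27), HIST1H2AC (-0.58), HIST2H4B (0.72), JUND (0.34), PFKP (-0.29), PLK1 (-0.27) and SLC19A1 (0.38). Without OVCAR5 DMSO replicate 1 the call was lost for ACTB (0.41), B2M (0.25), BOP1 (0.53), CDK17 (-0.50), DHRS2 (0.37), E2F1 (0.35), EGFR (-0.79), HIST1H2AC (-0.65), HIST2H4B (0.88), NEU1 (-0.47), PAX8 (0.32), PFKP (-0.34), PGK1 (0.23), PLK1 (-0.28), PPIA (0.34), RPS2 (0.56), SLC19A1 (0.42) and TXNRD1 (0.46). Without OVCAR5 DMSO replicate 2 the call was lost for ACTB (0.35), B2M (0.27), BOP1 (0.56), CD68 (0.36), CDK17 (-0.51), DHRS2 (0.34), E2F1 (0.32), EGFR (-0.71), HIST1H2AC (-0.69), HIST1H2BK (0.31), JUND (0.32), NAT10 (0.34), PFKP (-0.36), PGK1 (0.29), PLK1 (-0.27), PPIA (0.29), RPS2 (0.49), SLC19A1 (0.40) and TXNRD1 (0.51). Without OVCAR5 JQ1 replicate 1 the call was lost for ACTB (0.34), B2M (0.28), BOP1 (0.55), CD68 (0.37), CDK17 (-0.42), DHRS2 (0.38), E2F1 (0.33), EGFR (-0.80), FER (-0.83), HIST1H2AC (-0.73), HIST1H2BK (0.31), HIST2H4B (0.82), JUND (0.37), PAX8 (0.37), PFKP (-0.35), PGK1 (0.27), PPIA (0.30), RPS2 (0.46) and SLC19A1 (0.41). Without OVCAR5 JQ1 replicate 2 the call was lost for B2M (0.24), BOP1 (0.54), CD68 (0.43), CDK17 (-0.59), DHRS2 (0.33), E2F1 (0.35), EGFR (-0.70), HIST1H2AC (-0.60), NEU1 (-0.48), PFKP (-0.36), PGK1 (0.26), PLK1 (-0.22), PPIA (0.34), SLC19A1 (0.41) and TXNRD1 (0.45).

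Other settings ended calls of the difference as well, with the log2 difference under each given here. With quantile normalization the call was lost for ACTB (0.43), CASP9 (-0.24), CDK17 (-0.41), HES6 (-0.27), HIST1H2AC (-0.27), HIST1H2BC (-0.27), PGK1 (0.16), PPIA (0.10), RPS2 (0.12) and TXNRD1 (0.32). It was also lost for FTH1 (-0.13) and GAPDH (-0.11), which changed sign. With median centring the call was lost for CDK17 (-0.38), EGFR (-0.62), HIST1H2AC (-0.54), NEU1 (-0.41), PFKP (-0.22) and PLK1 (-0.14). With a pseudocount of 0.1 FPKM the call was lost for CDK17 (-0.58), HIST1H2BC (-0.34), HIST1H2BF (2.20), HIST2H2BE (-0.19), HIST2H4B (0.47) and TEX14 (0.19). With a pseudocount of 0.5 FPKM the call was lost for HIST2H4B (0.73) and RRAD (0.23). Without a filter on low values the call was lost for ACTB (0.38), B2M (0.26), CDK17 (-0.51), EGFR (-0.75), HIST1H2AC (-0.67), PLK1 (-0.27), PPIA (0.32) and RPS2 (0.53). In genes of at least 5 FPKM the call was lost for B2M (0.26) and CDK17 (-0.51). Without a variance trend the call was lost for B2M (0.26) and PLK1 (-0.27).

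Of the gene lists, 12 differed between the lines, which is what brings them here. The adjusted p was 1.264e-10 for cytosolic ribosomal proteins, 7.135e-06 for mitosis and G2/M genes, 1.067e-05 for MYC targets, 0.01333 for ribosome biogenesis, 0.02194 for ATF4 and unfolded protein response genes, 0.0308 for epithelial genes, 0.03142 for ERK feedback genes, 0.04042 for histone genes, and 0.04055 for mitotic and checkpoint kinases, NRF2 genes, semaphorins with ephrins, and housekeeping genes. With an estimated correlation these were 0.709, 0.326, 0.512, 0.326, 0.326, 0.326, 0.709, 0.326, 0.709, 0.326, 0.43 and 0.326. ATF4 and unfolded protein response genes were higher in A1847 in 10 cases of 31 and lower in 4 (11 and 5 adjusted over the list alone), epithelial genes in 3 and 16 of 24 (3 and 17 adjusted over the list alone), and ERK feedback genes in 3 and 12 of 20 (3 and 12 adjusted over the list alone). The same counts were 17 and 1 of 60 for ribosome biogenesis (17 and 1 adjusted over the list alone), 10 and 4 of 25 for histone genes (10 and 5 adjusted over the list alone). They were 1 and 8 of 22 for mitotic kinases (1 and 8 adjusted over the list alone), 11 and 8 of 27 for NRF2 genes (15 and 8 adjusted over the list alone). Finally they were 13 and 7 of 28 for semaphorins and ephrins (14 and 9 adjusted over the list alone) and 5 and 0 of 14 for housekeeping genes (4 and 0 adjusted over the list alone). The members that differed most were IMP3 (0.60), PES1 (0.59), BOP1 (0.54) and NOLC1 (0.54) in ribosome biogenesis and DDIT4 (2.83), SDF2L1 (1.62), ATF3 (1.34) and TRIB3 (1.04) among ATF4 genes. They were KRT7 (-2.19), CEACAM6 (2.11), PROM2 (1.05) and KRT19 (-0.97) among epithelial genes and EGR1 (-2.36), ETV5 (-1.32), FOSL1 (-1.32) and LIF (-1.16) among ERK feedback genes. Among histone genes they were HIST3H2A (1.98), HIST1H2AE (1.96), HIST1H2BF (1.42) and HIST1H1C (1.14), among mitotic kinases PBK (-0.74), MELK (-0.72), PLK4 (-0.71) and AURKA (-0.60), and among NRF2 genes AKR1B10 (2.75), OSGIN1 (-1.32), SRXN1 (-1.32) and GCLM (-0.97). Among semaphorins and ephrins they were SEMA3A (2.49), SEMA4A (1.30), EFNB2 (1.28) and SEMA7A (-1.22), and among housekeeping genes GAPDH (0.51), ACTB (0.38), PPIA (0.32) and PGK1 (0.26). The histone call was lost without A1847 DMSO replicate 1 (adjusted p = 0.0971), JQ1 replicate 1 (0.0971) or JQ1 replicate 2 (0.0605), and the ERK feedback call without A1847 JQ1 replicate 2 (0.0515). The NRF2 call was lost without any A1847 library or either OVCAR5 DMSO library (0.0515 to 0.0602), and the housekeeping call without any of the 4 DMSO libraries (0.0591 to 0.0713). The mitotic kinase call and the semaphorin call were lost without A1847 DMSO replicate 1 (0.11 and 0.0849), JQ1 replicate 1 (0.0611 and 0.054), JQ1 replicate 2 (0.0501 and 0.0501) or OVCAR5 DMSO replicates 1 (0.0602 and 0.0907) and 2 (0.0591 and 0.0591). With quantile normalization the calls were lost for cytosolic ribosomal proteins (0.319), ribosome biogenesis (0.0647), ATF4 genes (0.0647), mitotic kinases (0.0647), semaphorins (0.143), NRF2 genes (0.41) and housekeeping genes (0.801). With median centring they were lost for housekeeping genes (0.0587), mitotic kinases (0.0705), semaphorins (0.133), histone genes (0.137) and NRF2 genes (0.155). In genes of at least 5 FPKM they were lost for ATF4 genes (0.0617), NRF2 genes (0.276) and semaphorins (0.276), without a filter for semaphorins (0.28) and with a pseudocount of 0.1 FPKM for NRF2 genes (0.0684).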

How the results depend on the processing

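The test that left out symbols with several loci and short RNAs was chosen only after the result was seen, and the other alternatives were planned. Across the alternatives, the number of genes past the threshold ran from 5812 to 9757 in A1847 and from 5596 to 8695 in OVCAR5, each within 1.5 times its value in all 18, and from 6475 to 11344 on average over the lines, within 1.5 times in all 17. Kinases ran from 180 to 279 in A1847 and from 156 to 252 in OVCAR5. The count of genes whose response differed ran from 3041, with genes of at least 5 FPKM, where fewer genes are tested, to 6252. Leaving out 1 library gave 3135 to 5636 such genes, 92 to 200 such kinases and 7 to 13 lists that differed, the lowest being without OVCAR5 DMSO replicate 2 for genes and kinases and without A1847 DMSO replicate 1 or JQ1 replicate 2 for lists (7 each). Counts of changes of at least 2-fold rose with a pseudocount of 0.1 FPKM, which enlarges the change of low genes, to 1635 in A1847, 1500 in OVCAR5, 1332 on average and 1000 for the difference, and fell with genes of at least 5 FPKM to 686, 596 and 328 in A1847, OVCAR5 and the difference. In A2780 the genes at least 2-fold higher in both libraries ran from 253 to 506, the latter with a pseudocount of 0.1 FPKM, and those lower from 402 to 758. With an estimated correlation limma's camera passed 0 lists in A1847, 0 in OVCAR5, 0 on average and 0 for the difference, with 6, 3, 5 and 6 at an unadjusted p under 0.05, and quantile normalization left 6 lists that differed, where the cause was not tested.

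Of the values of named genes under the alternatives, 3937 of 3988 in A1847 kept their side of the threshold, with no called value changing sign, 32 lost the call and 19 gained one. In OVCAR5 these were 3902 of 3992, 56 and 34, and for the difference 3574 of 3779, 139 and 61. With quantile normalization the difference turned for FTH1 (0.52 to -0.13), GAPDH (0.51 to -0.11), RPL30 (0.05 to -0.40) and TNC (0.07 to -0.34), and with a pseudocount of 0.1 FPKM for RRAD (0.67 to -0.46). The cause was not tested. Among the values that kept their side, the sign changed in 120, of 55 genes, that passed the threshold under neither setting, the largest of them 0.35 in size. Of the values that passed under both settings, 37 of 3598 in A1847, 19 of 3291 in OVCAR5 and 27 of 2843 for the difference moved by over 1.5 times, the last including 10 with a pseudocount of 0.1 FPKM and 12 with quantile normalization.

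The labels number the replicates within each group, and nothing says that a number marks a shared day or batch. Replicate differences correlated at 0.261 between DMSO and JQ1 in A1847 and at 0.125 in OVCAR5, and between groups of different lines at 0.262, 0.234, 0.215 and 0.023. The last is under 0.1, and the numbers were not taken to pair the libraries. That value compares different lines, whereas the block pairs libraries within a line, where the correlations were 0.261 and 0.125. Pairing within a line is therefore not excluded, and whether the correlations reflect a shared day or batch stays open. With the replicate number as a block, 9127 genes passed in A1847, 8695 in OVCAR5, 9933 on average and 6252 for the difference (4726 without it), with 204 kinases for the difference (154 without it). Planned count tests were not run, because the files hold FPKM, and each line fitted alone gives no value for the average or the difference. Depth is known only in relative terms, so no limit from counting could be set on genes listed at 0.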

Other observations

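The comparison of kinases across the A1847 libraries with disagreeing labels and the setting that left out symbols with several loci and short RNAs were among the tests chosen only after the result was seen. Some changes in A1847 and OVCAR5 fell outside the lists that passed. The lists given first here were chosen after their values were seen. ERK pathway feedback genes had 4 rises and 12 falls among 20 in A1847 (5 and 12 adjusted over the list alone, adjusted p = 0.185), led by LIF (-3.11), HMGA2 (-2.77), ETV4 (-1.97) and FOSL1 (-0.99). In OVCAR5 they had 8 and 7 (8 and 7 adjusted over the list alone, adjusted p = 0.713), led by HMGA2 (-2.16), LIF (-1.95), ETV5 (1.55) and EGR1 (1.39). HMGA2, which encodes a chromatin architectural protein, fell in both lines. Among BCL2 family and apoptosis genes 9 rose and 13 fell of 28 in A1847 (9 and 13 adjusted over the list alone, adjusted p = 0.916), led by BCL2L11 (1.95), CFLAR (-1.65), BIRC3 (-1.26) and TNFRSF10B (1.23). In OVCAR5 the counts were 9 and 13 (9 and 13 adjusted over the list alone, adjusted p = 0.713), with changes in BCL2L11 (1.03), CFLAR (-1.02) and CASP9 (0.98). BCL2L11 encodes the pro-apoptotic protein BIM and CFLAR an inhibitor of death receptor signalling. Interferon response genes had 8 rises and 21 falls among 35 in A1847 (8 and 22 adjusted over the list alone, adjusted p = 0.246), led by IFI44 (-2.11), IRF7 (1.52), IFITM1 (-1.21) and IFIT3 (-1.06). In OVCAR5 there were 9 and 17 (9 and 18 adjusted over the list alone, adjusted p = 0.0849), led by IFITM1 (-3.12), IFITM2 (-2.93), OASL (-2.33) and IRF7 (2.32). Autophagy and lysosome genes had 19 rises and 12 falls among 42 on average over the lines (19 and 12 adjusted over the list alone), led by ULK1 (1.59), NEU1 (1.21), SQSTM1 (1.05) and MAP1LC3B (1.04) (adjusted p = 0.0476, or adjusted p = 0.488 with an estimated correlation). That call was lost without A1847 DMSO replicate 1 (adjusted p = 0.0644) or JQ1 replicate 1 (0.051), without a filter on low values (0.0705), with a pseudocount of 0.1 FPKM (0.0584) and with symbols at several loci and short RNAs left out (0.0629). All p-values here are from limma's camera.

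Markers of other cell types were mostly too low to be tested. Of 16 leukocyte markers only CD68 was tested, and it rose by 0.68 in A1847 and 0.28 in OVCAR5, where the call was lost without DMSO replicate 1 (0.23) or JQ1 replicate 2 (0.25). Of 11 endothelial markers 1 was tested and passed in neither line, and of 8 erythroid markers none reached the filter. Of 15 gastrointestinal epithelium markers 2 were tested, KRT20, which fell in OVCAR5 (-1.89), and CDX2, which rose in A1847 (0.44) and fell in OVCAR5 (-0.42). The call of CDX2 was lost in A1847 without DMSO replicate 1 (0.29) or JQ1 replicate 2 (0.32), and in OVCAR5 without DMSO replicate 1 (-0.44), DMSO replicate 2 (-0.41) or JQ1 replicate 1 (-0.30), with quantile normalization (-0.34) and without a filter on low values (-0.42, adjusted p = 0.0501 by limma). Of 10 ovarian and Muellerian markers 4 were tested. PAX8 rose (0.34) and FOLR1 fell (-0.39) in A1847, the latter call being lost without DMSO replicate 2 (-0.29), with median centring (-0.25) or with quantile normalization (-0.26). WFDC2 fell in OVCAR5 (-0.45).

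In A2780 further lists lay at the edge of random lists in both exposed libraries, given here for the library titled JQ1R and then the one titled JQ1. E2F targets and DNA replication genes had medians of -0.98 and -0.84 (percentiles 0 and 0), with 48 of 51 lower in both. Oxidative phosphorylation genes had -0.74 and -0.64 (percentiles 0 and 0), with 44 of 47 lower, and genes of homologous recombination and the Fanconi pathway -0.75 and -0.55 (percentiles 0 and 0). AP-1 and immediate early genes had 1.38 and 1.31 (percentiles 100 and 100), with 15 of 20 higher. Cholesterol biosynthesis genes had -0.80 and -0.39 (percentiles 0 and 1.28), with 16 of 24 lower. Fibroblast markers, of which the decorin gene DCN stood at 110.0 FPKM with DMSO, had -1.53 and -0.86 over 8 genes (percentiles 0 and 0.07).

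The 3 A1847 libraries with disagreeing labels are given as values, in the order titled JQ1, titled JQ1R and titled DMSO. IL7R stood at 0.126, 0.0396 and 60.6 FPKM, CDKN1A at 47.02, 125 and 8.93, and PEG10 at 486, 318 and 63.3. DHRS2 stood at 166, 41.6 and 8.36, PLAC8 at 18.2, 2.38 and 126, INHBA at 0.675, 0.156 and 13.02, and AURKA at 16.9, 11.1 and 49.9. FGFR3 stood at 13.7, 10.2 and 6.58. On the log2 scale the library titled DMSO correlated across genes at 0.976 and 0.978 with the A1847 DMSO libraries and at 0.934 and 0.934 with the A1847 JQ1 libraries. The library titled JQ1 correlated at 0.932 and 0.935 with the former and at 0.977 and 0.979 with the latter, and the library titled JQ1R at 0.905 and 0.905 and at 0.955 and 0.95.

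Of 498 kinases, 4 were at least 2-fold above all 6 other A1847 libraries in the library titled JQ1R and described as JQ1, a rule chosen after the values were seen, and 1 was at least 2-fold below them. In each of the other A1847 libraries 0 kinases met the rule in either direction, which is a count of values and not a test. PRKAA2, a catalytic subunit of the energy sensor AMPK, stood at 14.4 FPKM against 2.41 to 3.56 in the others, DYRK3 at 9.67 against 2.59 to 3.7, the fibroblast growth factor receptor FGFR4 at 69.2 against 23.97 to 32.1, and RIPK4 at 9.32 against 2.36 to 4.03. WNK4, which regulates ion transport, stood at 0.657 against 2.36 to 5.69. This library differs from the others in its labels, and whether it is the chronically exposed one is not settled by them.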
